A study of Mus musculus with 30 samples.

How the data were processed

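Bulk RNA sequencing libraries were made from 5 intestinal segments of WT and CKO mice, with 3 libraries for each segment and genotype. Per the labels, total RNA was extracted with TRIzol from 1 cm of the segment, poly(A) RNA was selected, and dUTP was used in the second strand so that libraries keep their strand. Poly(A) selection leaves transcripts without a tail out of the measurement. The submitters' processing notes name FastQC, cutadapt and DESeq2, without versions, and the genome build GRCm38 (mm10). The aligner, the counting tool, the gene annotation release and the use of strand in counting are not given in the sources used here. Genes with near-identical copies, such as defensins, immunoglobulin segments and MHC genes, share reads, so their counts are uncertain.

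The deposited table holds, per the file headers, the counts of each gene in each library and the authors' FPKM, with gene position and exonic length. It lists 55573 genes, of which 34604 were above 0 in any library, and 120 symbols occur more than once, so genes were followed by their Ensembl identifier. The deposited FPKM were checked against the counts: 100% equalled the count divided by the listed length and by the library's total count, in the usual units, within 0.005. The FPKM are therefore scaled to each library's total, and a few abundant transcripts move all other values of that library. The counts were whole numbers and were used for all main tests. Total counts were between 13399234 and 19226752 per library, and edgeR's TMM factors between 0.717 and 1.38. Statements of zero or few counts cover counting error only.

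Libraries were placed in groups by the labels, and each column was matched to its library by the library name in the labels. The replicate numbers 1 to 3 also come from the labels, which do not say that they stand for animals, and give the same batch, 1, to all 30 libraries. WT and CKO libraries were therefore not paired by number. For averages over segments, counts of the same genotype and number were summed, which ties segments by number although the labels state no such link. Before averaging, the libraries of each group were checked against each other by a chi-square test of their counts, and none was a copy of another.

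The design, the gene lists and the rule for naming genes were fixed before the data were examined. The tests fixed then were limma fits on log2(FPKM + 1). Because the table holds counts, edgeR replaced them, and limma became an alternative. Genes were kept with an FPKM of at least 1 in at least 3 of the libraries used. edgeR (4.0.16, in R 4.3.3 with the data.table package, version 1.17.8) was run with TMM scaling and its quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each segment was tested on its own 6 libraries, which leaves 4 residual degrees of freedom per gene. For averages over the small intestine or the colon, and for their difference, the counts of each genotype and replicate number were summed over segments or contrasted, so that 3 values per genotype were compared. The interaction of genotype and segment was tested over all 30 libraries, and segments of WT over the WT libraries. Fitted log2 values used edgeR's default prior count. The log2 levels per library, used for list levels and correlations, had a prior count of 2. Fitted log2 values against a group with few counts depend on the prior count, so for genes with almost no counts in a group the levels are given without a log2 value.

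Gsdmd levels were also compared by an exact permutation test. With 3 against 3 libraries this test cannot give a p under 0.1, two-sided.

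Gene lists were written by hand: 45 lists with 956 symbols, of which 942 were found. Each list with at least 5 tested genes entered the camera test of limma (3.58.1) with a preset correlation of 0.01 between genes, and was tested again with the correlation estimated from the data and with fry, both directional (whether the genes move on balance one way) and mixed (whether they change in either direction). fry does not compare a list with other genes. The estimated correlation lets libraries that share a shift in composition widen the error, and both results are given. List members were also counted after adjustment over the list alone.

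Genes were named by a rule. Gsdmd was always named. Next came up to 10 rises and 10 falls, the largest in log2, among genes past the threshold whose groups did not overlap, whose mean FPKM was at least 5 in either group and whose symbol was not a predicted or numbered model. In WT segments these were 5 and 5. Where fewer than 10 genes passed, the 10 with the smallest p were named. In each list described, up to 4 members with the smallest p were named. Calls outside the rule are named where a count was 5 or less, and were then chosen after their values were seen, as were Mt2, the class II genes by replicate number and their companions.

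Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, median-ratio scaling, the replicate number as a block, all 30 libraries in a single fit, an estimated correlation, fry, and leaving out each library or replicate number. limma with a pseudocount of 1, the test fixed first, was kept as another. Alternatives added after the data were seen were DESeq2 (1.42.0), removal of the trend with GC content and length by splines with 5 degrees of freedom, leaving out the ileum WT and CKO library with the most B cell RNA, leaving libraries out of the list tests, and the gasdermin list without Gsdmd. GC content was taken from the GRCm38 sequence of the listed genes.

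The procedure was tested on simulated data made from the duodenum counts of 10704 genes, with 50 genes changed at each fold size. edgeR recovered 10% of genes changed 1.5-fold, 56% at 2-fold, 96% at 4-fold and 96% at 8-fold, with 8 false calls among 137. limma recovered 38% at 2-fold and DESeq2 70%, the latter with 24 false calls among 165. For the small intestine average edgeR recovered 92% at 2-fold, for the difference of small intestine and colon 52%, and for the interaction 18%. Of 20 random lists 0 were called. Each gene and library was drawn independently, so correlation between genes, a GC trend and shifts shared by a replicate number were absent. Changed genes were drawn only above a minimum level. The recovered shares and the 0 lists therefore do not carry over to libraries with such structure. In the real duodenum libraries, divisions other than the real one called between 4 and 22 lists.

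Counts per exon, splicing and reads were not analysed here, so which exons remained in CKO transcripts was not examined. Some members of the lists described are not reported here.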

Results

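RNA was sequenced from 5 segments of the mouse intestine, the duodenum, jejunum, ileum, proximal colon and distal colon. The mice were wild type (WT) or carried a deletion of Gsdmd in intestinal epithelial cells, made with Villin-cre, a recombinase gene under the control of an epithelial promoter (conditional knockout, CKO). Unless the WT mice also carried Villin-cre, comparisons of CKO and WT cannot separate the deletion from the recombinase gene. The same holds for any difference in background between the WT and CKO mice. Each of the 10 groups of segment and genotype held 3 libraries, 30 in all. A library was made from poly(A) RNA of 1 cm of the segment, and the labels name no step that removed muscle, connective tissue or immune cells. Total counts per library ran from 13399234 in ileum CKO 1 to 19226752 in distal colon CKO 3. Genes encoded by the mitochondrial genome took between 2.31% and 18.2% of a library's counts. Replicate libraries of a group differed by more than counting noise, with a chi-square per degree of freedom between 9.755 and 170.9. The labels number the libraries of each group 1 to 3 and do not say whether they came from separate animals. The p-values below therefore measure only the spread between these samples, which may be technical. FPKM (fragments counted per length of exon and per size of the library) are given as mean ± SD with n = 3 libraries unless another n is stated.

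Gsdmd was examined first in every sample. It encodes gasdermin D, a protein that forms pores in the plasma membrane after inflammatory caspases cleave it. The gene (ENSMUSG00000022575) lies on the plus strand of chromosome 15 at 75862327 to 75867408 of GRCm38, with an exonic length of 2377 bases. In the duodenum its level was 295.8 ± 29.6 FPKM in WT and 39.45 ± 4.50 in CKO, which left 13.3% of the WT mean. In the jejunum it was 273.3 ± 39.0 in WT and 35.6 ± 5.24 in CKO, or 13.0%. In the ileum it was 165.0 ± 9.67 and 33.0 ± 2.62, or 20.01%. In the proximal colon it was 93.6 ± 6.79 and 21.4 ± 1.33, or 22.8%, and in the distal colon 192.3 ± 38.03 and 41.05 ± 6.08, or 21.4%. The lowest of the 15 WT libraries stood at 86.2 FPKM and the highest of the 15 CKO libraries at 47.6, so no library lay on the side of the other genotype. A permutation test of each segment gave exact p = 0.1, two-sided, the smallest that 3 against 3 libraries allow. Counts cover the whole gene, and the exons that the deletion removes are not given in the sources used here.

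**Figure D1:**
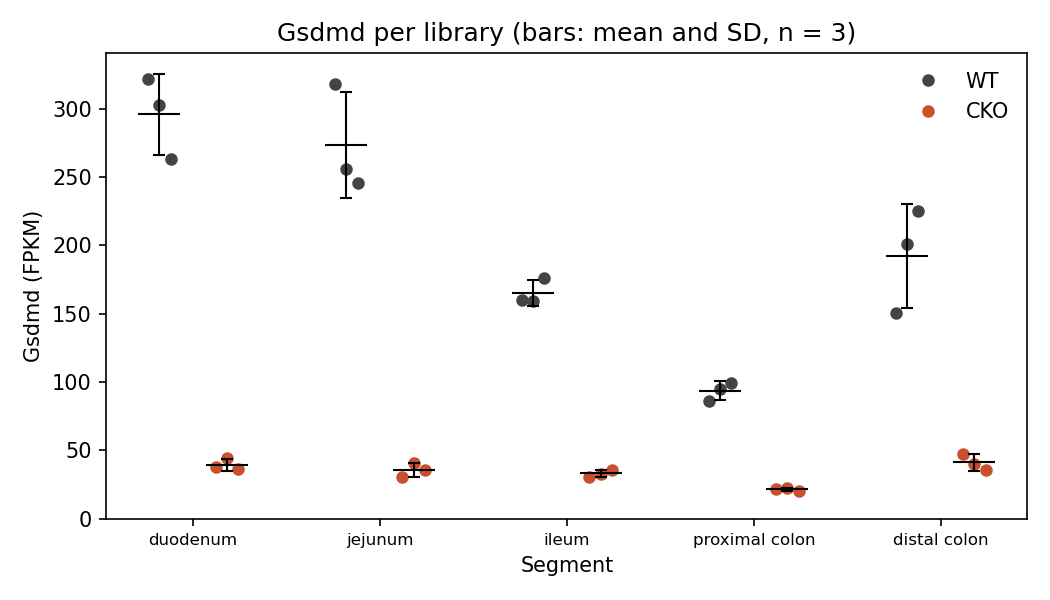
Gsdmd level in FPKM (vertical axis) in each of the 30 libraries (points) by segment and genotype, with the group means as lines. WT libraries lie at or above 86.2 FPKM and CKO libraries at or below 47.6.

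The fits across genes placed Gsdmd lower in CKO in each segment, with all 3 CKO libraries below all 3 WT libraries. The log2 difference was -2.93 in the duodenum (adjusted p = 0.000143), -2.86 in the jejunum (adjusted p = 0.000863) and -2.30 in the ileum (adjusted p = 0.0103). It was -2.08 in the proximal colon (adjusted p = 0.00032) and -2.34 in the distal colon (adjusted p = 0.0489). In the ileum the adjusted p rose to 0.0586 without WT 1, 0.0719 without CKO 1, 0.1002 without CKO 2 and 0.167 without CKO 3, within a range of 2.39e-35 to 0.167 over its alternatives, while the log2 difference stayed between -2.36 and -2.19 over the libraries left out. In the distal colon it rose to 0.160 without WT 2, 0.173 without CKO 1, 0.0764 without CKO 2 and 0.485 without CKO 3, within a range of 6.91e-23 to 0.485, with log2 differences between -2.53 and -2.13. Gsdmd in the distal colon also missed the threshold with median-ratio scaling (0.0610) and after a correction for GC content and length (0.0548).

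The duodenum comparison asked what the deletion changes in the segment next to the stomach. Of 11186 genes tested with edgeR, 3 passed an adjusted p of 0.05: Gsdmd, Igkv17-127 and Trp53inp1. Igkv17-127 (ENSMUSG00000076508, chromosome 6 at 67861153 to 67861659), a variable segment of the immunoglobulin kappa chain that plasma cells express, rose from 19.9 ± 2.74 FPKM in WT to 78.6 ± 13.0 in CKO (log2 1.96, adjusted p = 0.0147, higher in 3 of 3 CKO libraries). Its reads may be shared with related segments, so its identity is uncertain. Trp53inp1 (ENSMUSG00000028211, chromosome 4 at 11156431 to 11174379), a p53 target that acts in autophagy and stress responses, rose from 2.94 ± 0.159 to 7.99 ± 1.36 FPKM (log2 1.43, adjusted p = 0.0429, higher in 3 of 3 CKO libraries). Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18 at 60803848 to 60812652), did not pass, at 1185 ± 327 in WT and 373.4 ± 131 in CKO (log2 -1.69, adjusted p = 0.109). Pon3, a lactonase of the paraoxonase family (ENSMUSG00000029759, chromosome 6 at 5220852 to 5256286), stood at 7.66 ± 0.362 and 19.9 ± 5.45 FPKM. Tmem123, a membrane mucin, stood at 3.50 ± 0.327 and 7.64 ± 0.342. Adamdec1, a metalloprotease of the gut lamina propria, stood at 6.54 ± 0.274 and 13.0 ± 0.730 FPKM. For these, adjusted p was 0.109 and groups did not overlap.

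In the duodenum 2955 genes had an unadjusted p under 0.05, where chance alone would give 559.3 (1577 to 4261 with a library left out), and limma called 4 genes and DESeq2 1212. The edgeR count of 3 became 1 without WT 1, 1 without WT 2, 17 without WT 3, 24 without CKO 1 and 2399 without CKO 2. Igkv17-127 lost its call without WT 1 (adjusted p = 0.119) and without WT 2 (0.174), and after the GC and length correction (0.0833), within a range of 1.17e-13 to 0.174. Trp53inp1 lost its call without WT 1 (0.145), WT 2 (0.292), WT 3 (0.0617) and CKO 3 (0.147), after the correction (0.211) and with limma at both pseudocounts (0.0737 and 0.0821), within a range of 1.57e-08 to 0.292. Level and GC content were related across genes with Spearman coefficients of 0.352, 0.549 and 0.471 in duodenum WT 1, 2 and 3, and of -0.621, 0.0594 and -0.558 in CKO 1, 2 and 3. Genes are not independent replicates in these coefficients.

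Among the gene lists, 39 could be tested in the duodenum and 13 passed the camera test with its preset correlation. With an estimated correlation 0 passed, the smallest adjusted p being 0.830. Of the fry tests, the directional one called 0 lists and the mixed one, for changes in either direction, 20. Camera with its preset correlation called 22 lists in another division of the same 6 libraries. The fry tests were not run on other divisions, here or below. Of 8 MHC class II genes, 0 rose and 0 fell. Adjusted over the list alone, 0 rose and 4 fell, with a camera adjusted p = 0.00438 downward and an adjusted p = 0.830 with an estimated correlation. H2-DMa, which loads peptides on class II, stood at 29.35 ± 10.7 FPKM in WT and 9.12 ± 2.80 in CKO, and Ciita, the class II transactivator, at 2.37 ± 0.530 and 1.01 ± 0.434. Members of this list did not move together: H2-Aa stood at 40.2 ± 63.3 FPKM in WT and 36.5 ± 11.8 in CKO (log2 -0.15), and in WT 1 and WT 2 it was at most 5.28 and 6.01 in any segment, below every CKO library. Of 33 interferon-stimulated genes, 0 rose and 0 fell, and adjusted over the list alone 11 rose and 1 fell (camera adjusted p = 0.001 upward; adjusted p = 0.830 with an estimated correlation). In that list 26 genes had higher fitted levels in CKO, among them Oas2, a sensor of double-stranded RNA, at 1.13 ± 0.302 and 3.43 ± 1.16 FPKM, and the guanylate-binding protein gene Gbp7 at 1.27 ± 0.357 and 3.05 ± 0.885.

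Of 23 cholesterol synthesis genes in the duodenum, 0 rose and 0 fell, and adjusted over the list alone 0 rose and 10 fell (camera adjusted p = 0.00196 downward; adjusted p = 0.830 with an estimated correlation). Mvk, mevalonate kinase, stood at 5.85 ± 0.326 FPKM in WT and 2.68 ± 0.992 in CKO, and Mvd, which acts later in the same pathway, at 12.4 ± 3.53 and 5.43 ± 1.87. Of 32 fat absorption genes, 0 rose and 0 fell, and adjusted over the list alone 0 rose and 5 fell (camera adjusted p = 0.0142 downward; adjusted p = 0.830 with an estimated correlation). Soat2, which makes cholesterol esters, stood at 84.4 ± 9.59 and 49.2 ± 11.4 FPKM, and Mogat2, which rebuilds triglycerides, at 356.6 ± 29.2 and 232.3 ± 44.0. Of 12 crypt stem cell genes, 0 rose and 0 fell, and adjusted over the list alone 4 rose and 0 fell (camera adjusted p = 0.0181 upward; adjusted p = 0.830 with an estimated correlation). Olfm4, a crypt base marker, stood at 6.05 ± 3.46 and 28.4 ± 10.5 FPKM, and Cd44 at 1.63 ± 0.333 and 5.02 ± 2.74.

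Stomach genes varied widely between duodenum libraries. Tff2, a trefoil peptide of the stomach and of glands in the duodenum, stood at 1157 ± 1070 FPKM in WT and 6171 ± 5204 in CKO, and Gkn3, a gastric mucosa protein, at 284.8 ± 331 and 1488 ± 1357. The mean level of the stomach list, as log2 against the mean of the 6 duodenum libraries, was -0.00680, -0.323 and 0.773 in WT 1, 2 and 3, and -3.31, 1.56 and 1.31 in CKO 1, 2 and 3. Of its 9 genes 0 rose and 0 fell over all genes or adjusted over the list alone, and the median (-0.281), the mean (0.470) and the camera direction (downward, adjusted p = 0.890; adjusted p = 0.980 with an estimated correlation) differed in sign. The smooth muscle list was lowest in CKO 1, at -1.10.

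The jejunum comparison asked the same question in the next segment. Of 10949 genes tested, 1 passed, Gsdmd. Mt1, a metallothionein that binds zinc and copper (ENSMUSG00000031765, chromosome 8 at 94179082 to 94180327), stood at 81.3 ± 71.4 FPKM in WT and 590.8 ± 23.3 in CKO (log2 2.92, adjusted p = 0.601, higher in 3 of 3 CKO libraries). Pon3 stood at 6.68 ± 0.748 and 19.2 ± 6.72 FPKM (log2 1.61, adjusted p = 0.601), and H2-DMb2, a class II peptide loading gene, at 12.3 ± 2.95 and 3.90 ± 0.719 (log2 -1.56, adjusted p = 0.601). Pmaip1, a p53 target that promotes cell death, stood at 52.6 ± 8.15 and 90.3 ± 13.1 FPKM. Gata5, an intestinal transcription factor, stood at 29.8 ± 5.53 and 16.9 ± 3.49. Cyp4f16, a fatty acid hydroxylase, stood at 77.8 ± 4.97 and 49.1 ± 5.08. For these, adjusted p was 0.601 and groups did not overlap.

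In the jejunum 698 genes had an unadjusted p under 0.05, where chance would give 547.4 (185 to 4134 with a library left out), and limma called 1 gene and DESeq2 6. The edgeR count of 1 became 4 without WT 3 and 2435 without CKO 2. Level and GC content were related across genes with Spearman coefficients of 0.451, 0.335 and 0.267 in jejunum WT 1, 2 and 3, and of -0.467, 0.523 and -0.593 in CKO 1, 2 and 3. Of 38 lists, 5 passed camera, 0 with an estimated correlation (smallest adjusted p = 0.990), 0 with directional and 1 with mixed fry. Camera with its preset correlation called 22 in another division of the libraries. The count of lists became 8 without WT 2, 11 without WT 3 and 8 without CKO 1. Of 13 mitochondrially encoded genes, 0 rose and 0 fell, and adjusted over the list alone 9 rose and 0 fell (camera adjusted p = 5.96e-10 upward; adjusted p = 0.990 with an estimated correlation). mt-Nd1, a subunit of respiratory complex I, stood at 4237 ± 1159 FPKM in WT and 11190 ± 7616 in CKO, and mt-Nd5 at 1684 ± 511 and 4457 ± 2851. The mean level of this list, as log2 against the mean of the 6 jejunum libraries, was 1.64 in CKO 1, -0.681 in CKO 2 and 0.763 in CKO 3, and mitochondrial genes took 18.2% of the counts in CKO 1.

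Cholesterol synthesis genes in the jejunum had a median log2 of -0.22. Of 24 tested, 0 rose and 0 fell over all genes or adjusted over the list alone (camera adjusted p = 0.0480 downward; adjusted p = 0.990 with an estimated correlation). Mvk stood at 3.45 ± 0.792 FPKM in WT and 1.64 ± 0.807 in CKO. Of 8 MHC class II genes, 0 rose and 0 fell, and adjusted over the list alone 0 rose and 1 fell. Their median log2 was 0.07 and their mean -0.003, so median and mean differed in sign (camera adjusted p = 0.469 downward; adjusted p = 0.990 with an estimated correlation).

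In the ileum, where Paneth and goblet cells are abundant, 12346 genes were tested and 1 passed, Gsdmd. Mt1 stood at 53.7 ± 27.9 FPKM in WT and 914.0 ± 152 in CKO (log2 4.10, adjusted p = 0.104). Ido1, which degrades tryptophan, stood at 26.25 ± 1.61 and 14.98 ± 2.97 FPKM. Igfbp6, an insulin-like growth factor binding protein, stood at 7.07 ± 1.56 and 3.12 ± 0.715. Sprr2a2, an epithelial barrier protein, stood at 7.29 ± 1.29 and 13.6 ± 2.23. For these, adjusted p was 0.9997 and groups did not overlap. Hsph1, a heat shock protein, stood at 8.35 ± 0.665 and 12.3 ± 2.45 FPKM. Only 178 genes had an unadjusted p under 0.05, where chance would give 617.3 (161 to 338 with a library left out), and limma and DESeq2 called 2 genes each. The edgeR count became 0 without WT 1, 2 without WT 2, 7 without WT 3, and 0 without CKO 1, CKO 2 or CKO 3.

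Of 42 lists tested in the ileum, 11 passed camera, 0 with an estimated correlation (smallest adjusted p = 0.967), 0 with directional and 2 with mixed fry. Camera with its preset correlation called 26 in another division of the libraries. Without WT 3 the camera count of the real division was 18. Of 21 goblet cell genes, 0 rose and 0 fell over all genes or adjusted over the list alone (median log2 -0.37, camera adjusted p = 2.77e-07; adjusted p = 0.977 with an estimated correlation). Spdef, the transcription factor of goblet cell maturation, stood at 9.73 ± 1.58 FPKM in WT and 6.73 ± 1.64 in CKO, and Agr2, which folds mucin, at 229.6 ± 37.4 and 149.1 ± 53.4. Of 22 genes of the unfolded protein and integrated stress response, 0 rose and 0 fell over all genes or adjusted over the list alone, and 19 had higher fitted levels in CKO (median log2 0.23, camera adjusted p = 3.53e-06; adjusted p = 0.967 with an estimated correlation). Atf3, a stress-induced transcription factor, stood at 23.2 ± 6.32 and 39.1 ± 21.4 FPKM, and Sdf2l1, a chaperone of the endoplasmic reticulum, at 31.8 ± 2.31 and 38.3 ± 2.60.

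The B cell and Paneth cell lists in the ileum moved with single libraries. Cd79a, part of the B cell receptor, stood at 8.81 ± 11.7 FPKM in WT and 26.35 ± 39.7 in CKO, and Lyz1, the lysozyme of Paneth cells, at 654.2 ± 698 and 264.9 ± 198. Of 6 B cell genes, 0 rose and 0 fell over all genes or adjusted over the list alone (camera adjusted p = 0.00669 upward; adjusted p = 0.977 with an estimated correlation). The mean B cell level was 1.90 in WT 2 and 3.50 in CKO 1, as log2 against the mean of the 6 ileum libraries, and below 0 in the other 4. Of 18 Paneth cell genes, 0 rose and 0 fell over all genes or adjusted over the list alone (camera adjusted p = 0.0216 downward; adjusted p = 0.977 with an estimated correlation). The Paneth cell level was 2.24 in WT 2 and 1.31 in CKO 1, and reads of the near-identical defensin genes in this list are uncertain. Without ileum WT 2 the log2 difference of Ang4, an angiogenin of Paneth cells, turned from -1.78 to 1.62, and without CKO 1 that of Cd79a turned from 1.58 to -1.27.

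In the proximal colon 12898 genes were tested and 1 passed, Gsdmd. Mt1 stood at 78.7 ± 42.6 FPKM in WT and 536.7 ± 59.1 in CKO (log2 2.81, adjusted p = 0.139). Il18, a cytokine that inflammatory caspases activate, stood at 17.5 ± 1.21 and 26.9 ± 0.855 FPKM (log2 0.68), and Reg3g, an antibacterial lectin, at 779.6 ± 95.9 and 1211 ± 140 (log2 0.69). Tifa, an adaptor of nuclear factor kappa B signalling, stood at 27.85 ± 6.12 and 42.1 ± 3.50 FPKM (log2 0.65), and Pon2, another paraoxonase, at 31.5 ± 0.534 and 22.3 ± 2.15 (log2 -0.45). Adjusted p was 0.969 for Il18, Reg3g, Tifa and Pon2, whose groups did not overlap. At an unadjusted p under 0.05 there were 506 genes, where chance would give 644.9 (185 to 1326 with a library left out), and limma called 1 gene and DESeq2 2. The edgeR count of 1 became 2 without WT 2 and 11 without WT 3.

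Of 41 lists tested in the proximal colon, 15 passed camera, 0 with an estimated correlation (smallest adjusted p = 0.627), 0 with directional and 2 with mixed fry. Camera with its preset correlation called 21 in another division of the libraries. Of 19 antimicrobial and acute response genes, 0 rose and 0 fell, and adjusted over the list alone 2 rose and 0 fell (median log2 0.11, camera adjusted p = 0.000114; adjusted p = 0.627 with an estimated correlation). Saa3, a serum amyloid, stood at 19.6 ± 5.79 FPKM in WT and 32.7 ± 8.62 in CKO. Of 21 immediate early and heat shock genes, 0 rose and 0 fell over all genes or adjusted over the list alone, and 20 had higher fitted levels in CKO (median log2 0.26, camera adjusted p = 6.97e-06; adjusted p = 0.627 with an estimated correlation). Junb, a transcription factor induced by handling and growth signals, stood at 41.8 ± 7.70 and 53.6 ± 5.71 FPKM. Of 27 proliferation genes, 0 rose and 0 fell over all genes or adjusted over the list alone, and 4 had higher fitted levels in CKO (median log2 -0.18, camera adjusted p = 7.18e-06; adjusted p = 0.627 with an estimated correlation). Mcm2, a DNA replication helicase, stood at 4.33 ± 0.963 and 3.07 ± 0.390 FPKM.

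In the distal colon 13628 genes were tested and 1 passed, Gsdmd. Mt1 stood at 64.7 ± 16.7 FPKM in WT and 229.2 ± 39.0 in CKO (log2 1.72), Cdx2, the transcription factor of intestinal identity, at 11.6 ± 2.33 and 5.32 ± 1.08 (log2 -1.22), and Sparcl1, a matrix protein of stromal cells, at 67.8 ± 10.4 and 121.6 ± 14.8 (log2 0.75). Isx, an intestinal homeobox gene, stood at 6.42 ± 2.14 and 2.54 ± 0.566 FPKM, and Pon2 at 15.4 ± 1.16 and 11.3 ± 0.425. Adjusted p was 0.412 for Mt1, Cdx2, Sparcl1, Isx and Pon2, whose groups did not overlap except for Isx. At an unadjusted p under 0.05 there were 1261 genes, where chance would give 681.4, and limma called 1 gene and DESeq2 77. That excess was not stable: the 1261 became 702 without CKO 1, 726 without WT 3, 655 in a fit of all 30 libraries and 2320 without WT 1. The edgeR count became 12 without WT 3 and 0 without CKO 1, CKO 2 or CKO 3, and without WT 2 it was 1, a gene other than Gsdmd.

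Of 43 lists tested in the distal colon, 23 passed camera, 0 with an estimated correlation (smallest adjusted p = 0.509), 0 with directional and 0 with mixed fry. Camera with its preset correlation called 27 in another division of the libraries. Of 19 smooth muscle genes, 0 rose and 0 fell, and adjusted over the list alone 18 rose and 0 fell (median log2 0.75, camera adjusted p = 4e-24; adjusted p = 0.509 with an estimated correlation). Myh11, the myosin of smooth muscle, stood at 132.1 ± 58.2 FPKM in WT and 298.8 ± 52.8 in CKO, and Pgm5 at 14.4 ± 2.80 and 26.2 ± 5.56. The mean smooth muscle level, as log2 against the mean of the 6 distal colon libraries, was -0.0642, -0.408 and -0.611 in WT 1, 2 and 3, and 0.550, 0.544 and -0.0110 in CKO 1, 2 and 3. Of 20 fibroblast genes, 0 rose and 0 fell over all genes or adjusted over the list alone, and 20 had higher fitted levels in CKO (median log2 0.47, camera adjusted p = 8.68e-09; adjusted p = 0.509 with an estimated correlation). Dcn, decorin of connective tissue, stood at 30.7 ± 8.68 and 46.8 ± 4.70 FPKM. Of 21 myeloid cell genes, 0 rose and 0 fell over all genes or adjusted over the list alone, and 19 had higher fitted levels in CKO (median log2 0.35, camera adjusted p = 5.89e-07; adjusted p = 0.509 with an estimated correlation). Adgre1, a macrophage receptor, stood at 3.99 ± 0.784 and 5.76 ± 0.250 FPKM.

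The epithelial lists lay on the other side in the distal colon. Of 22 goblet cell genes, 0 rose and 0 fell, and adjusted over the list alone 0 rose and 3 fell (median log2 -0.27, camera adjusted p = 5.89e-07; adjusted p = 0.509 with an estimated correlation). Spink4, a secreted goblet cell peptide, stood at 831.0 ± 46.7 FPKM in WT and 596.6 ± 33.6 in CKO, and Tff3, a trefoil peptide of mucus, at 1421 ± 110 and 983.5 ± 128. Retnlb, a goblet cell protein that acts on bacteria, stood at 162.7 ± 74.4 and 70.9 ± 8.23 FPKM. Of 18 genes of the general epithelium, 0 rose and 0 fell, and adjusted over the list alone 0 rose and 1 fell (median log2 -0.31, camera adjusted p = 1.11e-06; adjusted p = 0.509 with an estimated correlation). Phgr1, an epithelial gene, stood at 307.0 ± 63.3 and 210.4 ± 23.3 FPKM.

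For the small intestine, the counts of each replicate number were summed over the duodenum, jejunum and ileum. Of 13291 genes tested, 1 passed: Gsdmd fell from 244.7 ± 65.5 to 36.0 ± 4.64 FPKM (n = 9 libraries, log2 -2.76, edgeR adjusted p = 0.000263, lower in 9 of 9 CKO libraries than in any WT library). Mt1 stood at 123.8 ± 118 FPKM in WT and 808.5 ± 206 in CKO (n = 9, log2 2.67, edgeR adjusted p = 0.315, higher in 9 of 9 CKO libraries than in any WT library). Pon3 stood at 7.74 ± 1.06 and 16.1 ± 6.78 FPKM, and Pmaip1 at 42.1 ± 15.95 and 72.2 ± 37.8, with edgeR adjusted p of 0.315 and 0.366. Their libraries overlapped between genotypes with the segments pooled. At an unadjusted p under 0.05 there were 1167 genes, where chance would give 664.6 (359 without CKO 3 and 3643 without CKO 2), and limma called 1 gene and DESeq2 36. The edgeR count of 1 became 7 without WT 3 and 888 without CKO 2.

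Of 43 lists tested for the small intestine, 10 passed camera, 0 with an estimated correlation (smallest adjusted p = 0.799), 0 with directional and 2 with mixed fry. Camera with its preset correlation called 28 in another division of the replicate numbers. Without WT 2 the camera count of the real division was 20. Of 22 genes of gasdermins and the inflammasome, 0 rose and 1 fell, Gsdmd, and adjusted over the list alone 0 rose and 1 fell (camera adjusted p = 0.000602; adjusted p = 0.799 with an estimated correlation). Without Gsdmd, the deleted gene, the other 21 did not pass (median log2 -0.15, camera adjusted p = 0.266; adjusted p = 0.980 with an estimated correlation). In the distal colon the list without Gsdmd passed, lower in CKO (median log2 -0.17, camera adjusted p = 0.0240; adjusted p = 0.664 with an estimated correlation). Pycard, the inflammasome adaptor, stood at 46.5 ± 7.00 FPKM in WT and 37.5 ± 5.02 in CKO (n = 9), and Nlrp6, an epithelial sensor, at 60.8 ± 8.10 and 51.4 ± 12.8. Of 13 mitochondrially encoded genes, 0 rose and 0 fell, and adjusted over the list alone 9 rose and 0 fell (median log2 0.80, camera adjusted p = 3.16e-13; adjusted p = 0.980 with an estimated correlation). mt-Nd5 stood at 1444 ± 341 and 2725 ± 2083 FPKM (n = 9).

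Both colon segments were averaged in the same way. Of 14300 genes tested, 1 passed: Gsdmd fell from 142.9 ± 59.3 to 31.2 ± 11.5 FPKM (n = 6 libraries, log2 -2.26, edgeR adjusted p = 0.0094, lower in 6 of 6 CKO libraries than in any WT library). This call missed the threshold without CKO 1 (adjusted p = 0.0679), CKO 2 (0.0569) and CKO 3 (0.0807), within a range of 2.31e-35 to 0.0807 over its alternatives. Mt1 stood at 71.7 ± 29.96 and 383.0 ± 174 FPKM (n = 6, log2 2.36, edgeR adjusted p = 0.151, higher in 6 of 6 CKO libraries than in any WT library). Pon2 stood at 23.45 ± 8.89 and 16.8 ± 6.16 FPKM, and Pcp4, a calmodulin regulator of neurons and muscle, at 11.1 ± 4.09 and 20.4 ± 5.57 (edgeR adjusted p = 0.9996 for both, with overlapping libraries). At an unadjusted p under 0.05 there were 491 genes, where chance would give 715.0 (277 to 1241 with a replicate number left out), and limma called 1 gene and DESeq2 18. The edgeR count became 2 without WT 2, 13 without WT 3, 0 without CKO 1 and 0 without CKO 3.

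Of 43 lists tested for the colon, 17 passed camera, 0 with an estimated correlation (smallest adjusted p = 0.186), 0 with directional and 0 with mixed fry. Camera with its preset correlation called 26 in another division of the replicate numbers. Of 19 smooth muscle genes, 0 rose and 0 fell, and adjusted over the list alone 15 rose and 0 fell (median log2 0.57, camera adjusted p = 1.28e-30; adjusted p = 0.450 with an estimated correlation). Tagln, a smooth muscle actin-binding protein, stood at 180.8 ± 84.0 FPKM in WT and 269.9 ± 140 in CKO (n = 6). Of 22 goblet cell genes, 0 rose and 0 fell over all genes or adjusted over the list alone (median log2 -0.19, camera adjusted p = 1.31e-06; adjusted p = 0.186 with an estimated correlation). Tff3 stood at 1113 ± 347 and 877.0 ± 142 FPKM (n = 6).

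The genotype differences of the small intestine and the colon were compared as the difference of both averages. Of 15254 genes 0 passed with edgeR, 791 had an unadjusted p under 0.05 where chance would give 762.7 (430 to 1872 with a replicate number left out), and limma called 0 and DESeq2 6. Gsdmd differed by -0.52 on the log2 scale (adjusted p = 0.804), Pon3 by 1.13 (adjusted p = 0.539) and Il1rn, the interleukin-1 receptor antagonist, by 0.95 (adjusted p = 0.539). Of 44 lists, 10 passed camera, 0 with an estimated correlation (smallest adjusted p = 0.938), 0 with directional and 0 with mixed fry. Camera with its preset correlation called 23 in another division of the replicate numbers. The camera count of the real division became 6 without CKO 3. Of 19 smooth muscle genes, 0 rose and 0 fell over all genes or adjusted over the list alone (median log2 -0.69, camera adjusted p = 2.30e-09; adjusted p = 0.938 with an estimated correlation), with Myh11 at -0.99. Of 12 adipocyte genes, 0 rose and 0 fell, and adjusted over the list alone 0 rose and 4 fell (median log2 -0.89, camera adjusted p = 4.73e-08; adjusted p = 0.938 with an estimated correlation). Cfd, a fat cell protease, was at -1.48 and Adipoq, adiponectin, at -1.42.

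The interaction test asked for genes whose genotype difference varied between any of the 5 segments. Of 15254 genes 4 passed with edgeR: Pon3 (adjusted p = 0.0142), Gm44250 (0.0142), Gm8989 (0.0142) and 9130208D14Rik (0.0385). Pon3 stood at 7.66 ± 0.362 FPKM in WT and 19.9 ± 5.45 in CKO in the duodenum and at 6.68 ± 0.748 and 19.2 ± 6.72 in the jejunum. Its levels were 8.88 ± 0.400 and 9.13 ± 0.101 in the ileum, 22.2 ± 1.61 and 19.9 ± 1.30 in the proximal colon, and 13.3 ± 1.60 and 14.6 ± 2.06 in the distal colon. Gm44250 (ENSMUSG00000107881, chromosome 6 at 5216258 to 5220486) lies next to Pon3 and showed the same contrast, with 7.78 in WT and 15.97 in CKO in the duodenum and 7.75 and 8.60 in the ileum. Gm8989 (ENSMUSG00000095457, chromosome 7 at 106323414 to 106330688) stayed below 1 FPKM outside the proximal colon, where it stood at 5.56 in WT and 4.72 in CKO. 9130208D14Rik (ENSMUSG00000086513, chromosome 7 at 105824223 to 105831515) stood at 1.17 and 3.16 in the duodenum and at 10.01 and 5.59 in the ileum. Reads of Gm44250, Gm8989 and 9130208D14Rik may be shared with other copies.

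At an unadjusted p under 0.05 the interaction test gave 1624 genes, where chance would give 762.7 (1045 to 3326 with a library left out), and limma called 3 and DESeq2 47. Over the 36 alternatives, Pon3 missed the threshold in 4 (adjusted p from 1.04e-12 to 0.0635), Gm44250 in 2 (6.14e-10 to 0.0502), Gm8989 in 8 (6.26e-06 to 0.480) and 9130208D14Rik in 22 (7.73e-13 to 0.162). These 36 do not include the GC and length correction. Without a duodenum library the count of 4 became 1 (WT 1), 2 (WT 2) or 9 (CKO 2). Without a jejunum library it became 0 (WT 1 or WT 2), 2 (CKO 1) or 455 (CKO 2).

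Mt1 and Mt2, neighbouring metallothionein genes, were compared in each segment. Mt1 stood at 236.3 ± 143 FPKM in WT and 920.8 ± 196 in CKO in the duodenum, beside the levels given above for the other segments. Mt2 (ENSMUSG00000031762) stood at 89.15 ± 80.7 and 106.7 ± 83.5 FPKM in the duodenum and at 52.4 in WT and 42.1 in CKO in the proximal colon. A fit over all 5 segments, added after the data were seen, gave Mt1 a log2 difference of 2.56 ± 0.376 (SE, unadjusted p = 0.00011, adjusted p = 0.274) and Mt2 one of 0.02 ± 0.539. Without WT 3 the differences were 3.18 ± 0.176 for Mt1 (adjusted p = 0.00135) and 1.02 ± 0.307 for Mt2 (adjusted p = 0.786). The same fit gave Gsdmd -2.60 (adjusted p = 8.77e-05).

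**Figure D2:**
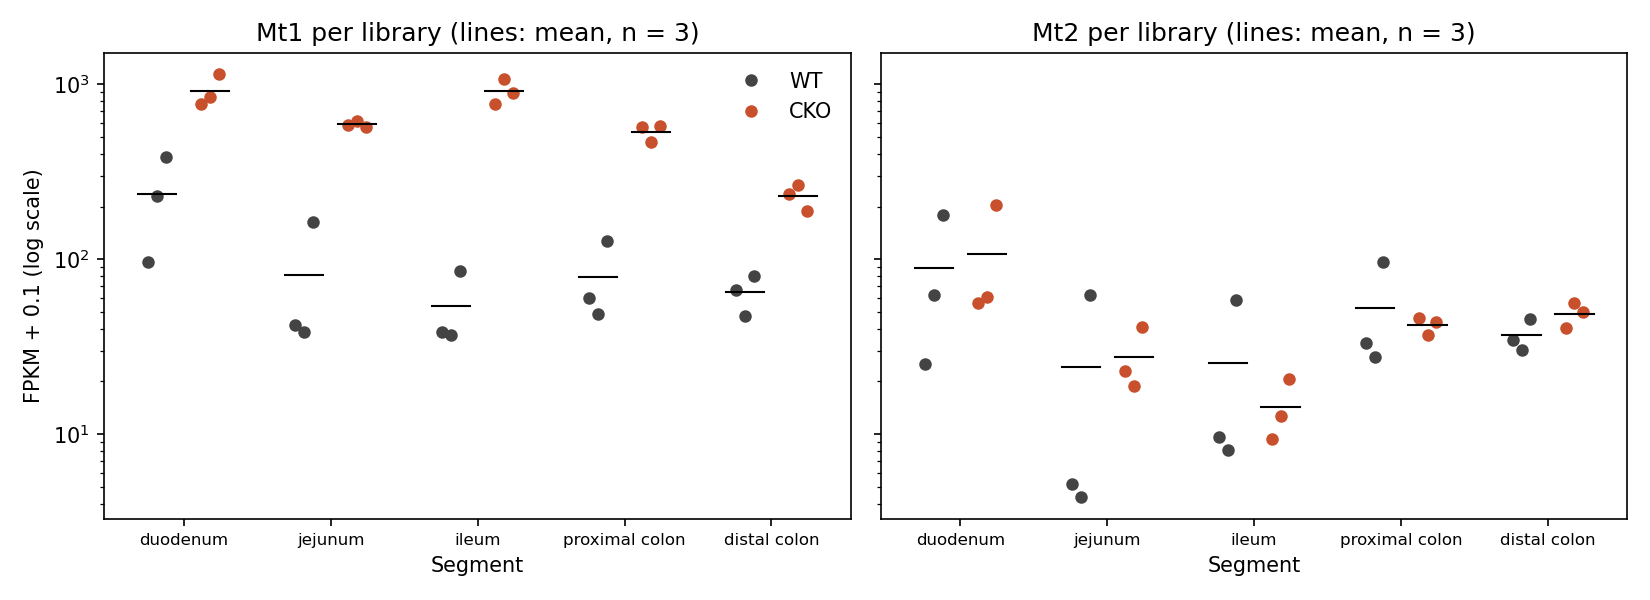
Mt1 and Mt2 in FPKM plus 0.1 (vertical axis, log scale) in each library (points) by segment and genotype. Mean Mt1 in the ileum was 53.7 FPKM in WT and 914.0 in CKO, and mean Mt2 was 25.4 and 14.1.

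Some MHC class II genes differed between replicate numbers within WT, and others did not. The mean of H2-Aa (ENSMUSG00000036594) over the 5 segments was 3.08 FPKM in WT 1, 4.57 in WT 2 and 152.1 in WT 3, and 94.7, 112.1 and 84.5 in CKO 1, 2 and 3. H2-Eb1 (ENSMUSG00000060586) stood at 9.39, 11.8 and 165.9 FPKM in WT 1, 2 and 3 and at 116.0, 145.3 and 101.6 in CKO 1, 2 and 3. Cd74, which the same cells express, stood at 1033, 1128 and 1145 FPKM in WT and at 696.4, 1021 and 703.3 in CKO. H2-DMa stood at 26.2, 30.9 and 26.6 FPKM in WT 1, 2 and 3, and Ciita at 4.66, 4.87 and 4.45, while H2-DMb2 was lowest in WT 3, at 9.46, against 15.25 and 20.5 in WT 1 and 2. Among other genes with the same contrast, Rps18, a ribosomal protein gene in the MHC region, stood at 1.87, 1.89 and 71.6 FPKM in WT 1, 2 and 3 and between 68.3 and 76.0 in CKO. Reads of class II genes of other haplotypes may be missed, so these levels are uncertain.

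**Figure D3:**
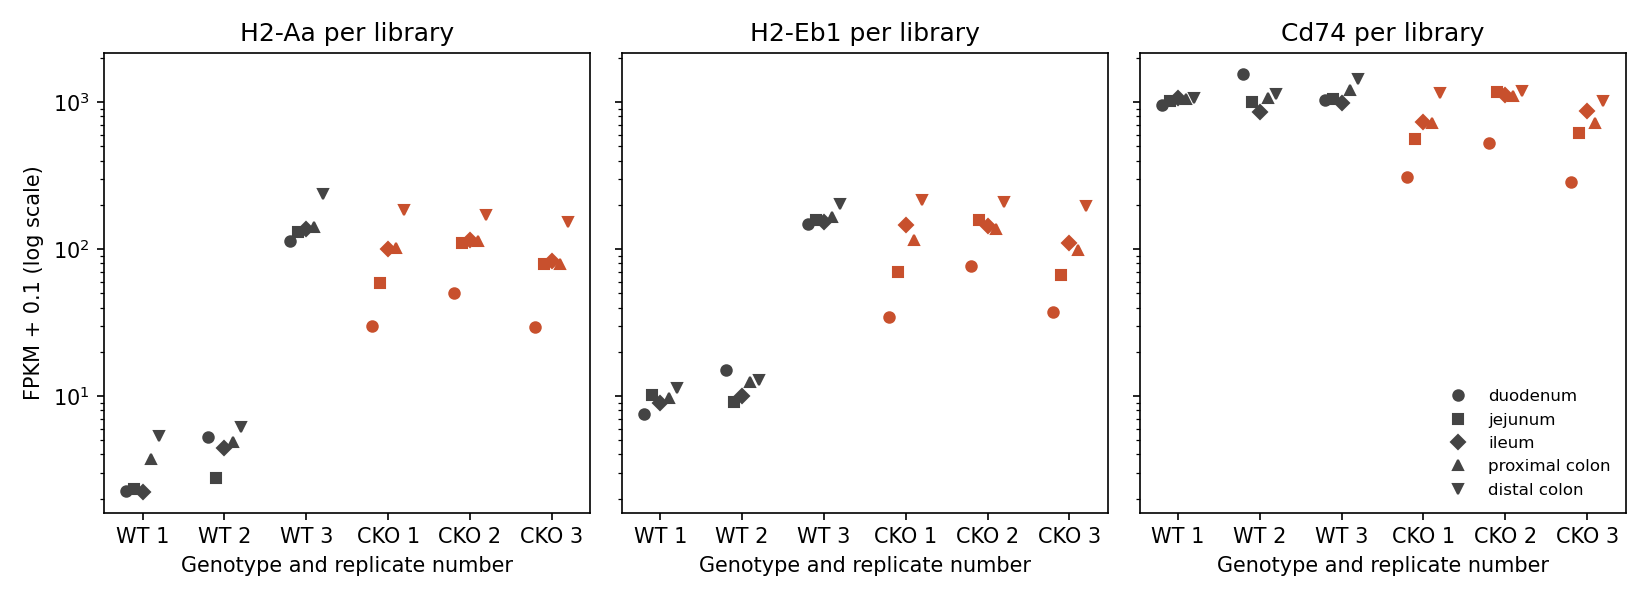
H2-Aa, H2-Eb1 and Cd74 (vertical axis, log scale) in each library by genotype and replicate number, with a marker for each segment. H2-Aa averaged 3.08 FPKM in WT 1 and 4.57 in WT 2, and 152.1 in WT 3, while Cd74 averaged between 1033 and 1145 in the 3.

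Neighbouring segments of WT mice were compared to set the genotype differences beside the regional differences of the gut. Between the jejunum and the duodenum, 2988 of 14229 genes passed, 1582 higher and 1406 lower in the jejunum. Slc34a2, a phosphate transporter, rose from 0.237 ± 0.134 FPKM in the duodenum to 135.2 ± 41.3 in the jejunum (log2 9.12, adjusted p = 4.21e-09), and Slc5a12, a lactate transporter, from 0.02 to 48.8 ± 22.7 (adjusted p = 3.50e-06, with 5 counts in the duodenum). Akp3, an intestinal alkaline phosphatase (ENSMUSG00000036500, chromosome 1 at 87124973 to 87127912), fell from 4294 ± 1316 to 1.59 ± 0.522 FPKM (log2 -11.42, adjusted p = 1.81e-07), and Tff1, a stomach trefoil peptide, from 1118 ± 431 to 0.137 (adjusted p = 1.32e-06, with 5 counts in the jejunum). For each of these genes all 3 libraries of one segment lay above all 3 of the other. Gsdmd differed by -0.15 (adjusted p = 0.641). Without duodenum WT 2 the count was 1877.

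Lists for the jejunum against the duodenum followed. Of 9 stomach genes, 0 rose and 9 fell, and adjusted over the list alone 0 rose and 9 fell (camera adjusted p = 6.70e-17; adjusted p = 0.00702 with an estimated correlation). Gkn2, a gastrokine, fell from 693.3 ± 247 to 0.223 FPKM. Of 21 mineral absorption genes, 4 rose and 12 fell, and adjusted over the list alone 4 rose and 14 fell (camera adjusted p = 6.08e-11; adjusted p = 0.0968 with an estimated correlation). Slc40a1, the iron exporter, fell from 147.2 ± 46.2 to 1.15 ± 0.0815 FPKM. Of 26 genes of fatty acid oxidation, 1 rose and 16 fell, and adjusted over the list alone 1 rose and 18 fell (camera adjusted p = 4.60e-08; adjusted p = 0.444 with an estimated correlation), with Acaa2, a mitochondrial thiolase, at 294.0 ± 69.6 FPKM in the duodenum and 50.9 ± 15.5 in the jejunum. Of 18 Paneth cell genes, 13 rose and 0 fell, and adjusted over the list alone 17 rose and 0 fell (camera adjusted p = 2.55e-09; adjusted p = 0.581 with an estimated correlation). Of 24 genes of gasdermins and the inflammasome, 10 rose and 3 fell, and adjusted over the list alone 11 rose and 3 fell (camera adjusted p = 0.0057; adjusted p = 0.715 with an estimated correlation). Gsdme, a gasdermin cleaved by caspase-3, rose from 0.543 ± 0.131 to 3.83 ± 0.819 FPKM, and Ninj1, which ruptures membranes, fell from 18.2 to 5.08.

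Between the ileum and the jejunum, 3867 of 14229 genes passed, 1901 higher and 1966 lower in the ileum. Fabp6, the bile acid binding protein (ENSMUSG00000020405, chromosome 11 at 43596049 to 43601540), rose from 7.23 ± 7.28 to 15940.0 ± 3509 FPKM (log2 10.83, adjusted p = 1.08e-05), and Slc10a2, the bile acid importer (ENSMUSG00000023073, chromosome 8 at 5083219 to 5105351), from 0.733 ± 0.541 to 237.5 ± 28.2 (log2 8.04, adjusted p = 4.60e-08). Lct, lactase (ENSMUSG00000026354, chromosome 1 at 128284756 to 128328318), fell from 365.2 ± 46.0 to 0.747 ± 0.715 FPKM (log2 -9.16, adjusted p = 5.34e-07), and Fabp1, a fatty acid binding protein, from 4465 ± 1499 to 37.5 ± 19.5 (log2 -7.25, adjusted p = 9.26e-06). All 3 libraries of one segment lay above all 3 of the other for Fabp6, Slc10a2, Lct and Fabp1. Gsdmd fell by 1.03 on the log2 scale (adjusted p = 0.00168). The count was 2335 without ileum WT 2 and 2405 without jejunum WT 3.

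Lists for the ileum against the jejunum followed. Of 25 cholesterol synthesis genes, 22 rose and 0 fell, and adjusted over the list alone 23 rose and 1 fell (camera adjusted p = 1.18e-21; adjusted p = 0.0635 with an estimated correlation). Fdft1, squalene synthase, rose from 7.35 ± 2.39 to 44.5 ± 3.57 FPKM. Of 32 fat absorption genes, 0 rose and 26 fell, and adjusted over the list alone 1 rose and 26 fell (camera adjusted p = 5.54e-16; adjusted p = 0.160 with an estimated correlation). Of 9 bile acid genes, 5 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000441; adjusted p = 0.160 with an estimated correlation), with Nr1h4, the bile acid receptor, at 26.8 FPKM in the jejunum and 138.0 in the ileum and its target Fgf15 at 0.377 and 17.2. Of 24 xenobiotic genes, 3 rose and 14 fell, also adjusted over the list alone (camera adjusted p = 7.50e-08; adjusted p = 0.384 with an estimated correlation), with Cyp2c66, a cytochrome P450, at 43.7 and 0.247 FPKM. Of 19 B cell genes, 13 rose and 0 fell, and adjusted over the list alone 16 rose and 0 fell (camera adjusted p = 0.00403; adjusted p = 0.692 with an estimated correlation). The B cell level was high in ileum WT 2, at 1.90.

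Between the proximal colon and the ileum, 4287 of 14229 genes passed, 2050 higher and 2237 lower in the proximal colon. Car1, a carbonic anhydrase (ENSMUSG00000027556, chromosome 3 at 14766216 to 14808368), rose from 8.14 ± 4.68 to 13100.0 ± 1319 FPKM (log2 10.51, adjusted p = 0.000108), and Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, from 0.883 to 208.1 ± 37.7. Of 26 brush border hydrolases, 1 rose and 22 fell, and adjusted over the list alone 1 rose and 23 fell (camera adjusted p = 5.82e-45; adjusted p = 0.0163 with an estimated correlation). Enpep, an aminopeptidase, fell from 580.1 ± 38.1 to 6.34 ± 0.376 FPKM. Of 32 fat absorption genes, 1 rose and 28 fell, and adjusted over the list alone 2 rose and 28 fell (camera adjusted p = 8.95e-39; adjusted p = 0.0181 with an estimated correlation), with Npc1l1, the cholesterol importer, at 236.8 and 0.917 FPKM. Of 19 sugar, peptide and amino acid transport genes, 0 rose and 18 fell, also adjusted over the list alone (camera adjusted p = 1.52e-35; adjusted p = 0.01001 with an estimated correlation), with Slc6a19, a neutral amino acid transporter, at 189.9 and 0.547 FPKM. Of 22 goblet cell genes, 12 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.946 with an estimated correlation), with Spdef at 9.73 and 44.3 FPKM. Gsdmd fell by 1.01 on the log2 scale (adjusted p = 0.00112).

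Between the distal and the proximal colon, 2583 of 14229 genes passed, 1076 higher and 1507 lower in the distal colon. Hoxb13, a homeobox gene of the posterior body (ENSMUSG00000049604, chromosome 11 at 96194316 to 96197447), rose from 0.117 to 128.7 ± 34.7 FPKM (adjusted p = 2.20e-08, with 13 counts in the proximal colon), and Mptx1, a mucosal pentraxin, from 2.10 to 1691 ± 181 (log2 9.58, adjusted p = 1.15e-06). Sptssb fell from 208.1 ± 37.7 to 0.717 FPKM. Of 26 genes of fatty acid oxidation, 0 rose and 18 fell, and adjusted over the list alone 0 rose and 19 fell (camera adjusted p = 1.98e-12; adjusted p = 0.110 with an estimated correlation). Of 24 xenobiotic genes, 1 rose and 12 fell, and adjusted over the list alone 1 rose and 16 fell (camera adjusted p = 1.24e-11; adjusted p = 0.183 with an estimated correlation), with Cyp2c55 at 1590.0 FPKM in the proximal and 5.70 in the distal colon. Of 6 pancreas acinar genes, 3 rose and 0 fell, and adjusted over the list alone 4 rose and 0 fell (camera adjusted p = 4.42e-05; adjusted p = 0.0136 with an estimated correlation), with Sycn, a granule protein, at 21.0 and 702.4 FPKM. Of 15 plasma cell genes, 7 rose and 0 fell, and adjusted over the list alone 10 rose and 0 fell (camera adjusted p = 0.00455; adjusted p = 0.702 with an estimated correlation), with Iglc2 at 59.6 and 203.6 FPKM. Gsdmd rose by 0.97 on the log2 scale (adjusted p = 0.0026).

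Between the whole small intestine and the colon, 9480 of 14229 genes passed, 4462 higher and 5018 lower in the small intestine. Apoa1, the main protein of high-density lipoprotein, stood at 19.3 ± 10.5 FPKM in the colon (n = 6) and 8798 ± 3759 in the small intestine (n = 9; log2 9.17, edgeR adjusted p = 2.75e-10), and Hao2, a hydroxy acid oxidase, at 86.7 ± 23.9 and 0.546 (log2 -8.00, edgeR adjusted p = 7.22e-13). Of 26 brush border hydrolases, 24 rose and 0 fell toward the small intestine, and adjusted over the list alone 25 rose and 0 fell (camera adjusted p = 9.40e-36; adjusted p = 0.0190 with an estimated correlation), with Treh, trehalase, at 0.638 and 161.7 FPKM. Of 27 proliferation genes, 0 rose and 27 fell, also adjusted over the list alone (camera adjusted p = 2.39e-07; adjusted p = 0.686 with an estimated correlation), with Mki67 at 21.5 ± 5.07 FPKM in the colon (n = 6) and 5.86 ± 3.55 in the small intestine (n = 9). Of 17 retinoid genes, 12 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000367; adjusted p = 0.448 with an estimated correlation), with Rbp2, a retinol binding protein, at 22.9 and 2091 FPKM. Gsdmd was higher in the small intestine by 1.26 on the log2 scale (edgeR adjusted p = 8.75e-07).

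**Figure D4:**
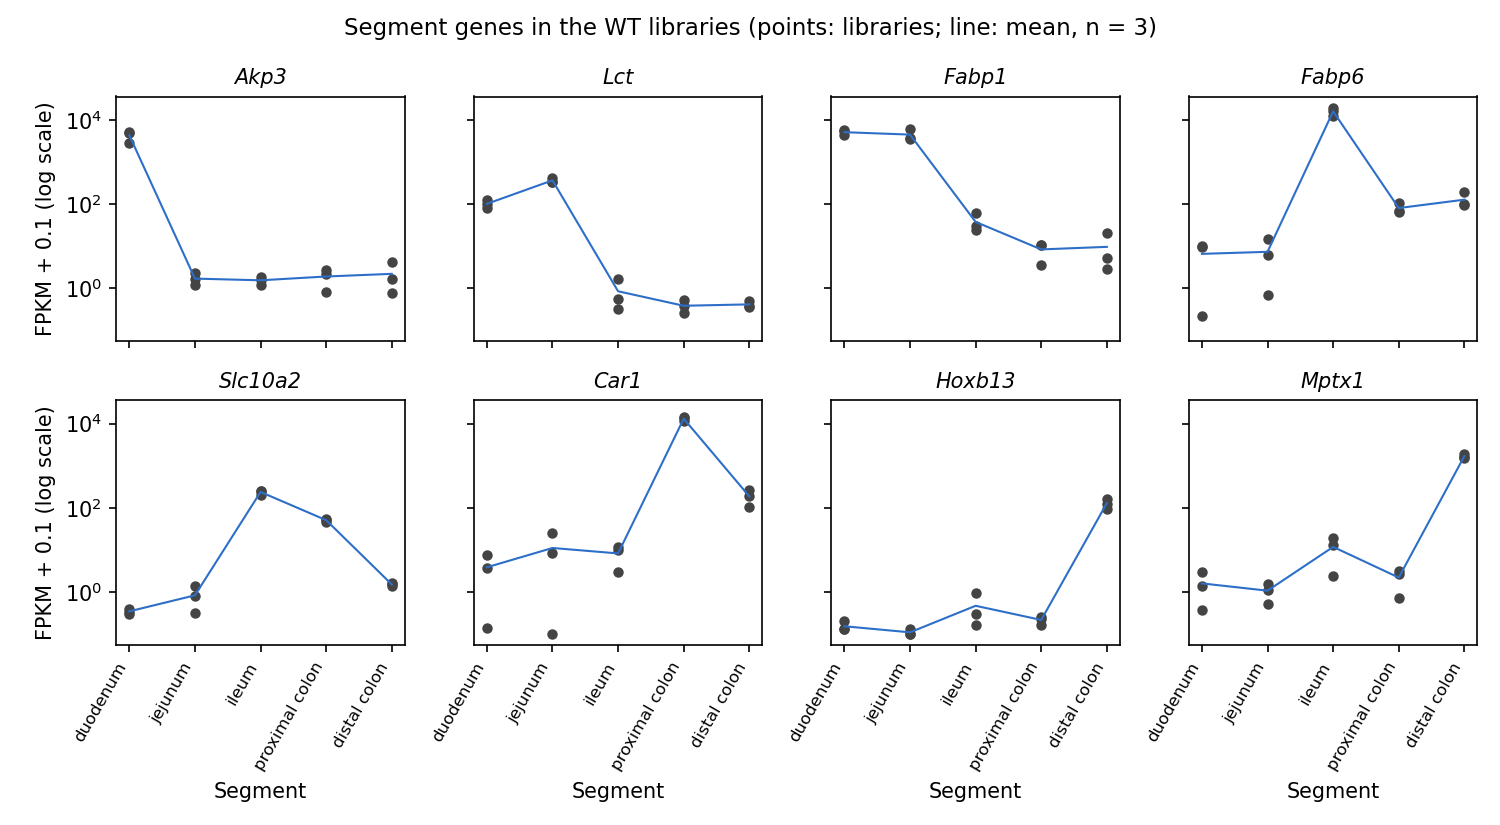
FPKM plus 0.1 (vertical axis, log scale) of 8 genes named in the segment comparisons in WT libraries (points, with the mean as a line) along the 5 segments. Akp3 peaks in the duodenum (mean 4294), Fabp6 in the ileum (15940.0), Car1 in the proximal colon (13100.0) and Mptx1 in the distal colon (1691).

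Over the 5 WT segment comparisons 85 list tests passed camera, 13 with an estimated correlation and 95 with directional fry. The mixed fry test called 30, 33, 35, 35 and 44 lists in the 5 comparisons, in the order above. Of 100 drawn divisions of the WT libraries, 77 called as many lists as the real one by camera with its preset correlation, up to 111.

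Whether the regional differences were also found in CKO was tested by the same contrasts in the CKO libraries, chosen after the data were seen, over 14006 genes tested in both genotypes. Of the genes called in WT, 97.6% had the same sign in CKO for the jejunum against the duodenum, 96.85% for the ileum against the jejunum, 99.2% for the proximal colon against the ileum, 99.25% for the distal against the proximal colon and 98.55% for the small intestine against the colon. Genes called in both genotypes in the same direction numbered 1387 for the jejunum against the duodenum, where 411.4 were expected from independent calls, and 2783 for the ileum against the jejunum, where 1384 were expected. They numbered 3070 for the proximal colon against the ileum (1103 expected), 1985 for the distal against the proximal colon (661.8 expected) and 7969 for the small intestine against the colon (6142 expected).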

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

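The results in this part passed a test of whether the WT and CKO difference itself varied between segments. The comparisons and lists in this part were fixed beforehand, but edgeR replaced limma once the table was seen to hold counts. Among the alternatives counted here, DESeq2 was added after the data were seen. In the interaction test with edgeR over 5 segments and 30 libraries, Pon3, Gm44250 and Gm8989 reached adjusted p = 0.0142 each, and 9130208D14Rik adjusted p = 0.0385. Over 36 alternatives Pon3 missed the threshold in 4, Gm44250 in 2, Gm8989 in 8 and 9130208D14Rik in 22, and the 4 calls became 0 without jejunum WT 1 or without jejunum WT 2. Pon3 stood at 7.66 FPKM in WT and 19.9 in CKO in the duodenum and at 8.88 and 9.13 in the ileum (n = 3 per group). Gm44250 lies beside Pon3 and moved with it, so both count as a single locus.

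For 10 gene lists the camera test of the small intestine difference minus the colon difference passed the threshold with its preset correlation. The adjusted p was 7.34e-12 for mitochondrially encoded genes (higher in the small intestine), 4.73e-08 for adipocyte genes and 2.30e-09 for smooth muscle genes (both lower), and 0.00857 for fibroblast genes. It was 0.0209 for MHC class II genes, 0.0209 for Paneth cell genes, 0.0311 for T cell and intraepithelial lymphocyte genes and 0.0311 for enteric neuron and glia genes. It was 0.0369 for genes of proximal small intestine identity and 0.0434 for MHC class I genes. With an estimated correlation 0 of the 10 lists passed, the smallest adjusted p being 0.938, and fry called 0, directional or mixed. With the preset correlation, each of the other 9 divisions of the replicate numbers called more lists by camera, from 12 to 23. These 10 therefore do not show that the genotype difference varied. Mitochondrial counts took 18.2% of jejunum CKO 1 and 10.3% of CKO 3, but 4.63% of CKO 2, within the 3.35% to 5.52% of jejunum WT. In the duodenum they took 7.04%, 6.62% and 10.5% of CKO 1, 2 and 3, above the WT libraries (5.16% to 5.34%). Within the MHC class II list, H2-Aa and H2-Eb1 were far lower in WT 1 and WT 2 than in WT 3 in every segment.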

How the results depend on the processing

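The tests with DESeq2, the GC and length correction, the omission of B cell-rich ileum libraries, the gasdermin list without Gsdmd, and the omission of libraries from the list tests were chosen after the data were seen. limma at a pseudocount of 1 was the test fixed beforehand, and edgeR took its place. The other alternatives were fixed beforehand. Where a count moved, the cause was not tested unless a value below shows it. Of 6268 alternatives for 353 results of named genes (a gene in a comparison), 5888 gave the same call and direction, 65 no longer passed, 308 newly passed and 7 changed direction.

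Counts of called genes moved with several settings. Without a filter the counts were 1681 in the duodenum, 166 in the jejunum, 2 in the ileum, 122 in the proximal colon, 276 in the distal colon, 67 for the small intestine, 89 for the colon, 133 for their difference and 797 for the interaction. DESeq2 gave 1212, 6, 2, 2, 77, 36, 18, 6 and 47 in the same order. A single fit of all 30 libraries gave 1987 in the duodenum, 4 in the jejunum, 2 in the ileum and 4 in the distal colon. limma gave 2 in the ileum at either pseudocount, and 3 in the distal colon at 0.1. Median-ratio scaling gave 0 in the distal colon, with Gsdmd at -2.36 (adjusted p = 0.0610). The GC and length correction gave 1 in the duodenum and 0 in the distal colon, with Gsdmd at -2.32 (0.0548). Without ileum WT 2 and CKO 1, the libraries with most B cell RNA, Gsdmd in the ileum was -2.27 (0.0556).

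limma on FPKM shifted the median of all genes in WT segments by 0.236 (log2) for the ileum against the jejunum, 0.175 for the proximal colon against the ileum and -0.377 for the small intestine against the colon. With these shifts included, its calls split into 3165 higher and 956 lower, 3254 and 1584, and 2383 and 8448, against 1901 and 1966, 2050 and 2237, and 4462 and 5018 with edgeR.

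The replicate number as a block gave 1 called gene in the duodenum, 0 in the ileum, 0 in the distal colon, 6 for the colon and 14 for the interaction. Gsdmd with the block was -2.29 in the ileum (adjusted p = 0.166) and -2.32 in the distal colon (0.146). The block ended the calls of Igkv17-127 and Trp53inp1 (0.0637 each) in the duodenum and of 9130208D14Rik in the interaction (0.0545). It brought Mt1, Igkv14-100 and Ighv14-2 in the colon and H2-DMa and Tgm2 in the interaction past the threshold, and changed no other call of a named gene. Pairing by number was checked by correlating, across genes, the deviations of libraries from their group mean. WT and CKO libraries of a segment with the same number gave a mean r of -0.0678 over 15 pairs, and 7 of 30 libraries correlated best with their own number. Segments of the same number gave 0.161 in WT and 0.0966 in CKO, over 30 pairs each, where 14 of 15 and 15 of 15 libraries did. Genes are not independent replicates in these coefficients. The main interaction fit took 30 libraries as independent and so ignored the correlation between segments.

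With an estimated correlation the lists called were 0 in every genotype comparison and 13 in WT segments, against 13, 5, 11, 15, 23, 10, 17 and 10 in the genotype comparisons and 85 in WT segments with the preset value. The directional fry test gave 0 in every genotype comparison. The mixed fry test gave 20 in the duodenum, 1 in the jejunum, 2 in the ileum and 2 in the proximal colon. It gave 2 for the small intestine, and 0 in the distal colon, for the colon and for their difference.

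Leaving out each library in turn gave the following ranges of called genes: 1 to 2399 in the duodenum, 1 to 2435 in the jejunum, 0 to 7 in the ileum, 1 to 11 in the proximal colon and 0 to 12 in the distal colon. They were 1 to 888 for the small intestine, 0 to 13 for the colon, 0 to 0 for their difference and 0 to 455 for the interaction. In WT they were 1877 to 3172 for the jejunum against the duodenum, 2335 to 4334 for the ileum against the jejunum, 3213 to 4674 for the proximal colon against the ileum, 1733 to 2824 for the distal against the proximal colon and 8726 to 9525 for the small intestine against the colon. Gsdmd ranged from -3.01 to -2.86 in the duodenum, -2.94 to -2.75 in the jejunum, -2.36 to -2.19 in the ileum, -2.19 to -1.99 in the proximal colon and -2.53 to -2.13 in the distal colon. Lists ranged from 7 to 20 in the duodenum, 5 to 11 in the jejunum, 11 to 18 in the ileum, 11 to 21 in the proximal colon, 18 to 27 in the distal colon, 9 to 20 for the small intestine, 16 to 20 for the colon, 6 to 12 for their difference and 81 to 91 in WT segments. In the duodenum the list count was 20 without CKO 1 and 7 without CKO 2.

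The 7 changes of direction were in the ileum. Ang4 went from -1.78 to 0.11 without both WT 2 and CKO 1. Left out one at a time, WT 2 moved Ang4 to 1.62, Mptx2 from -1.78 to 0.56 and Defa20 from -0.99 to 0.30, and CKO 1 moved Cd72 from 1.12 to -0.29, Cd79b from 1.60 to -1.24 and Cd79a from 1.58 to -1.27. At the other end of the ranges over left-out libraries, Ang4 was -3.27, Mptx2 -2.38 and Defa20 -1.58 without CKO 1, and Cd72 was 1.80, Cd79b 3.37 and Cd79a 3.54 without WT 2.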

Other observations

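Gasdermins other than Gsdmd were spread along the WT gut. Gsdme stood at 0.543 ± 0.131 FPKM in the duodenum, 3.83 ± 0.819 in the jejunum, 21.2 ± 2.84 in the ileum, 2.62 ± 0.215 in the proximal colon and 0.673 ± 0.162 in the distal colon (n = 3 each). Gsdmc2 stood at 0.727, 16.6 ± 7.42, 93.4 ± 88.9, 229.3 ± 26.0 and 328.9 ± 197 FPKM in the same order, and Gsdmc4 at 1.17, 24.4 ± 10.8, 163.0 ± 171, 239.7 ± 29.97 and 620.1 ± 276. Il18, whose product leaves cells through gasdermin pores, stood at 116.7 ± 10.5, 64.2 ± 5.18, 23.25 ± 5.31, 17.5 ± 1.21 and 87.3 ± 7.11 FPKM. Nlrp6 stood at 58.0, 56.8, 67.5, 101.3 and 109.1 FPKM, and Nlrp9b, an inflammasome sensor of the gut, at 25.5, 47.2, 43.7, 26.2 and 24.9.

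Some genes of the circadian clock, chosen after their values were seen, differed between replicate numbers. The mean of Nr1d1, a repressor of the clock, over 5 segments was 18.9, 17.05 and 34.6 FPKM in WT 1, 2 and 3 and 15.9, 26.8 and 32.5 in CKO 1, 2 and 3 (edgeR adjusted p = 3.15e-06 for differences between replicate numbers within a genotype). Tef, a clock output, stood at 2.98, 2.31 and 4.46 in WT and at 2.82, 5.04 and 5.63 in CKO (adjusted p = 4.57e-06). Dbp stood at 1.41, 1.04 and 2.11 in WT and at 1.36, 2.48 and 3.75 in CKO (adjusted p = 0.0013). Arntl stood at 6.67, 6.67 and 4.95 in WT and at 5.502, 4.62 and 4.27 in CKO (adjusted p = 0.151), and Per3 (adjusted p = 0.154), Ciart (0.170) and Npas2 (0.277) did not pass either. The hour at which tissue was taken is not given in the sources used here.

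The tests of Cd74, of Gsdmd as a sign of exchanged or misplaced samples, of Mt2, also with each replicate number left out, and of the GC and length correction were chosen only after the result was seen. The tests of the linked MHC region and of the Mt1 neighbours, and the divisions of the samples, were written before their results.

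H2-Aa and H2-Eb1 were far lower in WT 1 and WT 2 than in WT 3 in all 5 segments, with a log2 range of 5.24 for H2-Aa over the 6 combinations of genotype and number. Fewer cells with class II are argued against by Cd74, whose range was 0.826, and an exchange of WT and CKO samples by Gsdmd, which lay on the other genotype's side in 0 libraries. A linked difference of the MHC region of chromosome 17 was tested over the 50 genes with the smallest p for differences between numbers within a genotype, class II genes left out: 3 lay in the region, Rps18, H2-K1 and Hspa1a, where 0.531 were expected (exact hypergeometric p = 0.0160). In all, 10 of the 50 lay on chromosome 17, where 2.59 were expected, so the excess was not confined to the region. The 7 outside include Hmga1, with the same contrast (2.71, 1.91 and 7.00 FPKM in WT 1, 2 and 3). Another, Rps2, was low in WT 1 alone (2.12 FPKM, against 196.6 in WT 2). A haplotype shared by WT 1 and WT 2 does not account for Rps2. Another MHC haplotype in WT 1 and WT 2 is a candidate for H2-Aa, H2-Eb1 and region genes with that contrast, such as Rps18. It was not separated from a wider difference of chromosome 17. Gene counts cannot separate poorly matching reads from lower expression.

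Mt1 was higher in CKO in all 5 segments, by 2.56 (log2, SE 0.376) in the fit over all of them, which did not pass the threshold (adjusted p = 0.274). A metal or stress response that raises both metallothionein genes stays open: Mt2 differed by 0.02331 (SE 0.539) over all libraries, but by 1.02 (SE 0.307) without WT 3, where Mt2 averaged 88.7 FPKM against 21.4 in WT 1 and 26.45 in WT 2. The GC content or length trend of the libraries is argued against by the corrected Mt1 difference of 2.57. A response of Mt1 alone to the loss of Gsdmd, or a difference that came with Villin-cre, was not tested and stays open. The test of a linked block of chromosome 8 around Mt1 did not decide: 6 of 52 neighbours within the window had an unadjusted p under 0.05, where 3.10 were expected (exact hypergeometric p = 0.0879). The bound written before that test, a p of 0.05 or more, would have counted against the block, but it was too weak, because the count lies above the expected one.

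Without CKO 2 the duodenum gave 2399 called genes and the jejunum 2435. A WT library in place of CKO 2 is argued against by Gsdmd, which stood at 16.9% and 16.6% of the lowest WT library. After the correction for GC content and length the counts without CKO 2 were 94 in the duodenum and 400 in the jejunum, so a GC or length trend may account for part of these calls. Genes at an unadjusted p under 0.05 went from 4261 to 2539 in the duodenum and from 4134 to 2497 in the jejunum, where chance would give 542.6 and 536.9; whether the same genes stayed was not tested. Whether the trend came from RNA quality, library preparation or tissue was not tested, and the single batch value in the labels offers no split.

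Other divisions of the same samples were counted for each result. With 10 divisions the design cannot give a share under 0.05, and this holds for all genotype comparisons and for neighbouring WT segments. In the duodenum 1 of 10 gave as many called genes (real 3, highest other 1), in the jejunum 3 (real 1, highest other 3), in the ileum 4 (1 and 1), in the proximal colon 2 (1 and 1) and in the distal colon 2 (1 and 1). For the small intestine it was 2 (1 and 1), for the colon 3 (1 and 1), for their difference 10 (0 and 2) and for the interaction 1 (4 and 3). In the duodenum 2955 genes had an unadjusted p under 0.05 in the real division and at most 984 in another, so 1 of 10 gave as many.

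For WT segments 1 of 10 divisions gave as many called genes in each neighbouring pair, with 2988, 3867, 4287 and 2583 in the real one and at most 1, 0, 0 and 0 in the others. For the small intestine against the colon 1 of 100 drawn divisions gave as many, the real one, and another called 5813. This excludes chance only if the 15 libraries can be exchanged freely. The divisions did not keep libraries of a number together, and 14 of 15 WT libraries correlated best with their own number.

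Lists behaved otherwise. In the duodenum 4 of 10 divisions called as many lists (real 13, highest other 22), in the jejunum 10 (5 and 22), in the ileum 10 (11 and 26), in the proximal colon 6 (15 and 21) and in the distal colon 3 (23 and 27). For the small intestine it was 9 (10 and 28), for the colon 8 (17 and 26) and for their difference 10 (10 and 23). These designs too cannot give a share under 0.05. In each of these 8 comparisons another division called more lists than the real one, which points to a structure of the samples whose cause was not tested. For WT segments 77 of 100 gave as many lists (real 85, highest other 111), so chance is not excluded for that count.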
